A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

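Small RNA was sequenced from dorsal skin of rainbow trout (Oncorhynchus mykiss) sampled at 45 days. The 6 libraries form 2 groups of 3, wild-type fish with black skin (WR) and a yellow mutant stock (YR), as the labels give genotype and skin colour. Per the labels' protocols, total RNA was extracted with Trizol, ligated to adapters at both ends, reverse transcribed, amplified and sequenced on an Illumina HiSeq Xten. Nothing in the labels says that the libraries of a group come from separate fish, so p-values measure only the spread between these samples, which may be technical.

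The authors' deposited table lists 1939 mature miRNAs, 709 with known names and 1230 predicted. The deposited whole-number count of each miRNA in each library was used as it stands. Library totals of counts ran from 8245698 to 10336991. The authors also deposited a TPM score per library, which equals the count divided by a library constant 1.04 to 1.05 times smaller than the table's own total, so that the TPM of a library sum to between 1039894 and 1052569. The deposited TPM of a miRNA with a count of 0 is written as a small positive number, and was set to 0 here. The authors' deposited table further holds a log2 fold change of group means, a p-value and an adjusted p-value, and the test behind them is not given in the sources used here. The aligner, the miRNA database, the genome build and the way reads with several matches were counted are not given in the sources used here either. A known name stands for a family number and a suffix, where x rows match 5p arms and y rows 3p arms in let-7 and miR-92, and z has no stated arm. In 338 cases a listed sequence repeats that of an earlier entry. These make 231 sequences listed more than once, 205 of them with identical counts in all 6 libraries, so such entries are not independent. No genome was used, so no coordinates are given. Predicted miRNAs are given by their sequence, not by the identifiers of the authors' table.

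Before the data were examined, the test was set to limma on log2 TPM, or to edgeR if the values were counts. Because they are counts, edgeR 4.0.16 (R 4.3.3) was used: TMM scaling, quasi-likelihood test of YR against WR, no replicate term, Benjamini-Hochberg adjustment, threshold 0.05. The 834 miRNAs with a mean of at least 1 TPM over the 6 libraries were tested, 428 known and 406 predicted. Those left out hold 0.0369% of the counts. Fold changes are those of edgeR, after TMM scaling, whereas TPM means keep the authors' library scale, so that the ratio of 2 TPM means differs from the fold change. The SE of a log2 fold change is its size divided by the square root of the F statistic. Lists of miRNAs, fixed before the data were examined from textbook knowledge, were tested with camera (limma 3.58.1, preset correlation 0.01) on edgeR log2 CPM with a prior count of 2, with adjustment over the 14 lists with at least 3 tested members. The choice of these values in place of log2 TPM was made after the unit was known and before any list was tested. The lists were pigment cell, epidermis, dermis and mesenchyme, skeletal muscle, red blood cell, white blood cell, nerve and neural, endothelium, liver and gut, sensory cluster, let-7, miR-17-92 and paralogous clusters, Hox clusters, miR-430, an imprinted cluster of placental mammals, insect and land plant. A family number may stand on more than 1 list. The last 2 lists had 0 entries, and miR-430 had 1 tested entry and was not tested as a list. Ratios of 5p to 3p arms were tested with limma on log2((5p TPM + 1)/(3p TPM + 1)) in 112 pairs. Shares of the counts were compared by exact permutation tests, 2-sided, which cannot go below p = 0.1 with 3 libraries against 3.

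The miRNAs named were chosen by a rule fixed beforehand: the 10 most abundant; per direction up to 10 known and 5 predicted of largest fold change among those past the threshold with a mean of at least 10 TPM and no overlap between groups; up to 4 most abundant members of each list and any member past the threshold; and arm ratios past the threshold. Not every member that the rule gives for a list is named, and those named outside the rule are marked as such. Where a group had no read of a miRNA, the fold was computed against a floor of 3 counts over the group and is a lower bound. Floors and 95% intervals cover counting error only.

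Within each group every pair of replicates differed by far more than sampling noise, with chi-square per degree of freedom from 65.2 to 527, so each library counts as 1 replicate. The steps were tested on simulated data. For the comparison of YR with WR, with the dispersions of the real libraries, 834 miRNAs and 200 changed, the edgeR step recovered 14% of 2-fold and 73% of 4-fold changes, and 3.3% of its calls were false. The arm step, on 150 simulated pairs with 40 changed, recovered 100% and 4.8% of its calls were false. Its simulated shifts were larger than the 0.793 found for miR-15. Its simulated spread was smaller than that of many real pairs (SD up to 1.961 in WR, for miR-29). It thus does not measure how many smaller shifts the arm step misses. Alternatives were other pseudocounts, filters, scalings and variance models, limma, DESeq2 1.42.0, a replicate term, and leaving out each library. Alternatives chosen after seeing the data were 1 entry per distinct sequence, leaving out the imprinted-cluster names, library totals without TMM, offsets for GC content, and the 10 most abundant miRNAs of each library itself. Summing by family number and arm changes nothing here, since each known entry is already such a sum.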

Results

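The data are counts of mature miRNAs in dorsal skin of 45-day-old rainbow trout, 3 libraries from black wild-type fish (WR) and 3 from yellow mutant fish (YR). The library totals were 8656356, 9150819 and 9209869 counts in WR and 10239947, 8245698 and 10336991 in YR, so that 1 read was worth 0.101 to 0.127 TPM. The question set by the series is which miRNAs differ between skin of the 2 colours.

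The 8 most abundant miRNAs stood in the same order in both groups. miR-199-x, a miRNA of mesenchyme, led, at 287600 ± 16920 TPM in WR and 308200 ± 39110 TPM in YR (SD, n = 3 each). It was followed by miR-181-x, miR-26-x, miR-10-x of the Hox clusters, miR-27-y, miR-204-x, miR-211-z, and the epithelial miR-205-x. By the mean over all 6 libraries let-7-x and miR-199-y came next, but in WR miR-200-y and miR-21-x stood above both. The 10 of highest mean over all 6 libraries held 64.9% ± 1.53 of the counts in WR and 69.0% ± 2.21 in YR (SD, n = 3 each; exact permutation test, 2-sided, p = 0.1, the smallest this design allows; adjusted over 22 shares 0.314). This choice favours miR-199-y, ranked 15 in WR and 9 in YR. With the 10 most abundant of each library itself, an alternative chosen after seeing the data, the share was 66.1% ± 1.89 in WR and 69.1% ± 2.08 in YR (exact p = 0.2). miR-204-x and miR-211-z, both expressed in pigment cells of other vertebrates, stood at 39820 ± 4675 against 39750 ± 5648 TPM and at 36270 ± 4854 against 36350 ± 5331 TPM (WR against YR). The authors' deposited table lists both with the same sequence, so their levels are not independent. Predicted miRNAs held 0.50% ± 0.0124 of the counts in WR and 0.447% ± 0.0274 in YR (exact p = 0.1).

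Skin of the yellow mutant had lower levels of 4 known and 22 predicted entries, which together hold 20 distinct sequences. Fold changes below are TMM-scaled and TPM means are not, so their ratios differ. miR-122-x, the main miRNA of liver, stood at 44.0 ± 6.90 TPM in WR and 9.18 ± 3.81 TPM in YR (SD, n = 3 each), and fell 4.14-fold after TMM scaling (log2 fold change -2.05, SE 0.295; edgeR adjusted p = 0.0201). miR-11213-x, at 36.2 ± 4.30 and 7.75 ± 2.62 TPM, fell 3.99-fold after this scaling (edgeR adjusted p = 0.0201). miR-196-z, of the Hox clusters, at 9.60 ± 3.66 and 1.32 ± 0.430 TPM, fell 6.17-fold (edgeR adjusted p = 0.0371). Of the 6 known miRNAs that rose after TMM scaling, those with a mean of at least 10 TPM were miR-455-y (1.82-fold), miR-99-z (1.73-fold), miR-199-y (1.66-fold), miR-101-y (1.51-fold) and miR-26-x (1.34-fold). The other, miR-3074-x, named after its values were seen, had a mean of 8.79 TPM and rose 3.32-fold (edgeR adjusted p from 0.0218 to 0.0409 for the 6). Before that scaling, miR-199-y stood at 23040 ± 4794 TPM in WR and 31930 ± 693 TPM in YR, and miR-101-y at 1647 ± 194 and 2103 ± 184 TPM. When the 428 known miRNAs were tested alone, 0 passed by edgeR (52 at an unadjusted p under 0.05), and the adjusted p of the 8 named by the rule ran from 0.0752 for miR-122-x and miR-11213-x to 0.344.

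**Figure D1:**
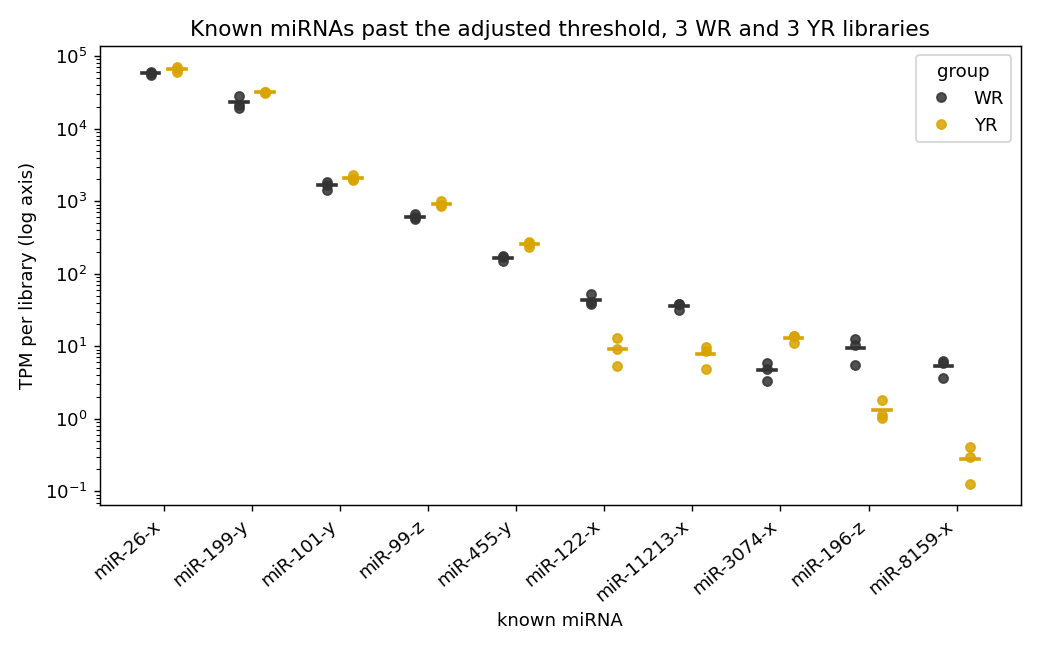
TPM of the 10 known miRNAs past the adjusted threshold (log axis), with a point per library and a bar at the mean of each group of 3. WR and YR points do not overlap for 9 of them, and miR-26-x overlaps.

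Among predicted miRNAs, TCTGGATCGATCTGTACGACA had 371, 309 and 323 reads in the WR libraries and 0, 1 and 1 in YR, a ratio of 535 (95% counting interval 148 to 4420; edgeR adjusted p = 0.00387). TTGGCAATAACTCCAATGTGAT, at 23.8 ± 3.13 and 1.87 ± 0.205 TPM, fell 10.8-fold after TMM scaling (SD, n = 3 each; edgeR adjusted p = 0.00387). The sequence TATTCCCTATGTAGAGCACTA, listed 4 times, was higher in YR by 2.32- to 2.52-fold after TMM scaling. ATCTCAATCAGTGATGGAACATCT, at 14.5 ± 2.43 and 28.7 ± 2.37 TPM, was higher by 2.34-fold after it (edgeR adjusted p from 0.0218 to 0.0343 for these 5 entries). In all, 44 of 834 miRNAs passed, 18 higher and 26 lower in YR, and they hold 34 distinct sequences. Of these 44, 10 were known, 6 higher and 4 lower; 43 had no overlap between groups, which 28.3% of all tested miRNAs also had and chance would give 10%.

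How many rose depended on the scaling. TMM factors were 1.19, 1.08 and 0.987 in WR and 1.02, 0.913 and 0.841 in YR, and the median log2 fold change of all miRNAs was -0.03 with TMM and -0.26 with library totals alone, which called 1 higher and 29 lower. With the 5 most abundant left out of the totals the split was 9 higher and 30 lower, with GC offsets 6 and 38, and with limma on log2(TPM + 1) 4 and 37. That limma setting changes the test as well as the scaling. Other settings stayed closer to the main split, with 16 higher and 27 lower by median-of-ratios scaling and 32 and 44 by DESeq2. Quantile normalization with limma gave 9 and 17. miR-26-x, miR-199-y, miR-455-y, miR-99-z and miR-101-y kept their direction but lost the call with library totals alone (adjusted p from 0.0551 to 0.279), while miR-122-x, miR-11213-x and miR-196-z kept theirs. Of the 15 entries named by the rule that passed in the main result, known and predicted, 5 kept the call with library totals alone and 10 lost it. As only 1 higher call was left there, predicted miRNAs higher in YR lost it too. The count also depended on single libraries: it was 118 without WR replicate 1 (31 higher, 87 lower), 1 without WR replicate 2, 5 without WR replicate 3, and 2, 18 and 9 without YR replicates 1, 2 and 3. Without WR replicate 1, 14 of the 15 named entries kept the call, and miR-26-x lost it (log2 fold change 0.24, edgeR adjusted p = 0.113). Most of the 15 lost it without any other library. The call was kept by 1 without WR replicate 2 and by 2 without WR replicate 3. It was kept by 1, 3 and 2 without YR replicates 1, 2 and 3, and by 2 with a replicate term. An adjusted p under 0.05 stands beside 96 miRNAs in the authors' deposited table, and 27 of the 49 of them tested here passed here. Another 17 passed here but not there. Among these were miR-455-y, miR-99-z, miR-199-y, miR-101-y and miR-26-x, with the authors' adjusted p from 0.391 to 0.841. The predicted entries named above as higher in YR had 0.13 to 0.153 there. For miR-122-x, miR-11213-x and miR-196-z, which fell, the authors' adjusted p was 0.0025 to 0.00316.

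miRNAs of the sensory cluster, miR-183, miR-96 and miR-182, which are transcribed together and mark sensory hair cells, were lower in YR in all 5 tested entries. miR-183-x stood at 1086 ± 221 TPM in WR and 533.6 ± 82.3 in YR, miR-182-x at 650.0 ± 46.9 and 369 ± 72.3, and miR-96-x at 310.0 ± 150 and 132 ± 35.0 (SD, n = 3 each). The list's median log2 fold change was -0.71 (camera adjusted p = 0.0162, lost with an estimated correlation, adjusted p = 0.667). Over all miRNAs 0 members passed by edgeR, with 2 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma. Adjusted over the list alone 2 fell, miR-183-x and miR-182-x. Without WR replicate 1, 3 fell over all miRNAs (camera adjusted p = 0.00458; adjusted p = 0.487 with an estimated correlation), and without WR replicate 3 the list missed the threshold (camera adjusted p = 0.0629).

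Epidermal miRNAs leaned the same way. Of 17 entries, 13 had negative log2 fold changes. By edgeR 0 passed, over all miRNAs or adjusted over the list alone, with 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma. miR-203-y, a miRNA of keratinocyte differentiation, stood at 12290 ± 1669 TPM in WR and 8096 ± 587 in YR, miR-200-y at 29920 ± 2995 and 22990 ± 1202, miR-184-y at 24920 ± 3054 and 19470 ± 3688, and miR-205-x at 36240 ± 5776 and 34810 ± 4642 (SD, n = 3 each). After TMM scaling the log2 fold changes of miR-203-y, miR-200-y and miR-184-y were -0.375, -0.156 and -0.12. That of miR-205-x was positive, at 0.172. The list's median log2 fold change was -0.23 (camera adjusted p = 0.173, and 0.82 with an estimated correlation). The call was reached in 12 of 26 alternatives, among them without WR replicate 1 (adjusted p = 0.00458, or 0.487 with an estimated correlation; median -0.45, 6 fell), with GC offsets (0.0179) and with library totals alone (0.0176), over a range of 0.00458 to 0.82. The 12 are not all separate tests. Limma on log2(TPM + 1), with its trend, without it and robust, gave the same list test (camera adjusted p = 0.0196 each). The list's share of the counts was 10.7% ± 0.0936 in WR and 8.75% ± 0.781 in YR (exact permutation test p = 0.1, adjusted 0.314).

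Neural miRNAs leaned the other way, with 12 of 13 log2 fold changes positive and a median log2 fold change of 0.41 (camera adjusted p = 0.00913; adjusted p = 0.667 with an estimated correlation). Over all miRNAs 0 passed by edgeR, with 5 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma. Its 4 most abundant members were miR-128-y, a miRNA of neurons, at 3750 ± 1291 TPM in WR and 3900 ± 715 in YR, miR-338-y at 579.8 ± 140.1 and 660 ± 35.8, miR-7-x at 155.2 ± 72.0 and 142.1 ± 21.9, and miR-9-z at 58.3 ± 9.83 and 89.5 ± 30.2 (SD, n = 3 each). miR-219-x, a miRNA of myelinating glia, named after its values were seen, rose when adjusted over the list alone, from 1.22 ± 0.760 to 5.25 ± 1.27 TPM. Without WR replicate 1 the median was 0.26, 3 entries were negative and the list missed the threshold (camera adjusted p = 0.114), as with a mean of at least 10 TPM (0.137). With library totals alone the median was 0.19. The list's share of the counts was 0.451% ± 0.0983 in WR and 0.478% ± 0.0687 in YR (exact permutation test p = 0.8, adjusted 0.926).

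**Figure D2:**
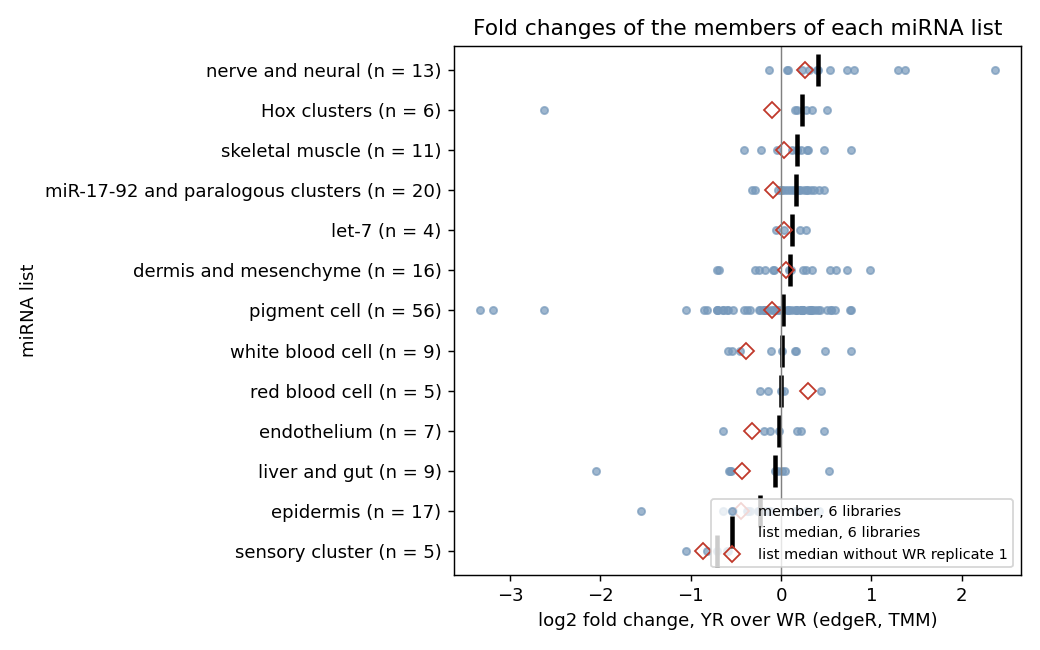
log2 fold change of YR over WR for the tested members of 13 of the 14 lists (points), the imprinted-cluster list with its median of -2.95 left out, with the list median over 6 libraries (black bar) and without WR replicate 1 (red diamond). Of the 13 drawn, the sensory cluster has the lowest median, -0.71, and the neural list the highest, 0.41.

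The pigment cell list had 56 tested entries, 28 with positive and 28 with negative values. miR-101-y rose and miR-196-z fell, over all miRNAs and adjusted over the list alone, and 54 did not pass. The median was 0.02 (-0.20 with library totals alone), the mean -0.19 and the test upward (camera adjusted p = 0.868). The mean was pulled down by miR-434-y and miR-434-x (log2 fold changes -3.335 and -3.196), named after their values were seen. Both had WR replicate 1 over 3 times every other library, and stood at -0.085 and -0.105 without it. The list's most abundant members were miR-27-y, at 45160 ± 8366 and 42860 ± 3987 TPM, miR-204-x, miR-211-z and miR-125-x (SD, n = 3 each). Without WR replicate 1, 1 entry rose and 12 fell, and the test turned downward (camera adjusted p = 0.42). In the dermis and mesenchyme list, miR-199-y rose and the other 15 did not pass (median 0.10, -0.11 with library totals alone; camera adjusted p = 0.457). Without WR replicate 1, 2 rose and 3 fell (median 0.06). miR-21-x stood at 27750 ± 5052 and 19970 ± 764 TPM and miR-143-y at 11540 ± 8096 and 9017 ± 1972. In the liver and gut list, miR-122-x fell and the other 8 did not pass (median -0.07, 0.05 with quantile normalization and -0.43 without WR replicate 1). Its camera adjusted p was 0.173, 0.00813 with a mean of at least 10 TPM, and adjusted p = 0.667 with an estimated correlation. miR-192-x stood at 308 ± 98.1 and 178 ± 24.9 TPM and miR-194-x at 48.3 ± 9.47 and 27.9 ± 3.06, which fell without WR replicate 1. In the Hox list, miR-196-z fell and the other 5 entries did not pass (median 0.23, mean -0.19, test upward, camera adjusted p = 0.737). The Hox median without WR replicate 1 was -0.10 and the test downward (camera adjusted p = 0.774), and with library totals alone the median was 0.02. These single calls also hold adjusted over each list alone.

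Markers of other cells gave 0 calls by edgeR, over all miRNAs and adjusted over each list alone. At an unadjusted p under 0.05 there were 3 in the white blood cell list, 2 in miR-17-92 and its paralogs, 1 each in skeletal muscle and endothelium, and 0 for red blood cell and let-7. DESeq2 and limma called 1 each in the white blood cell list and 0 in the others. The white blood cell list had 9 entries, a median of 0.01, a mean of -0.01 and a downward test (camera adjusted p = 0.98). It includes miR-146-x, a miRNA of the innate immune response, at 23640 ± 7860 TPM in WR and 14100 ± 524 in YR (SD, n = 3 each). Without WR replicate 1, 3 of the list fell, among them miR-146-x (log2 fold change -0.98, edgeR adjusted p = 0.00136), and the list's median was -0.39. In the endothelium list, also without that library, 2 fell, the median was -0.32 and the test turned downward (camera adjusted p = 0.522). Camera adjusted p was 0.457 for skeletal muscle (11 entries; miR-206-y 10830 ± 1837 and 10810 ± 3339 TPM), 0.944 for red blood cell (5 entries; miR-451-x 168 ± 33.8 and 148 ± 42.5 TPM) and 0.865 for endothelium (7 entries, median -0.03, upward in the test; miR-126-y 6991 ± 49.5 and 8331 ± 1470 TPM). It was 0.457 for let-7 (4 entries) and 0.157 for miR-17-92 and its paralogs (20 entries). Skeletal muscle passed without YR replicate 3 (0.0166) and miR-17-92 without WR replicate 3 (0.023); over all 6 libraries with an estimated correlation, adjusted p = 0.886 for each. The tests of both turned downward without WR replicate 1 (0.988 and 0.774). miR-430-y, a miRNA of early embryos, stood at 2.15 ± 0.921 and 1.96 ± 0.404 TPM.

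Names from an imprinted miRNA cluster of placental mammals were read mainly in 1 library. The list took 33570 counts in WR replicate 1, 1068 and 608 in the other WR libraries, and 733 to 973 in the YR libraries; miR-127-y alone had 23313 counts in WR replicate 1 and 326 to 602 elsewhere. All 32 tested entries had negative values, with a median log2 fold change of -2.95 (camera adjusted p = 0.00913; adjusted p = 0.886 with an estimated correlation and 0.138 with library totals alone). With quantile normalization the median was -0.79 (adjusted p = 0.000759). By edgeR 0 passed, over all miRNAs or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma. Without WR replicate 1 the median was 0.05 and camera gave the opposite direction (adjusted p = 0.424).

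**Figure D3:**
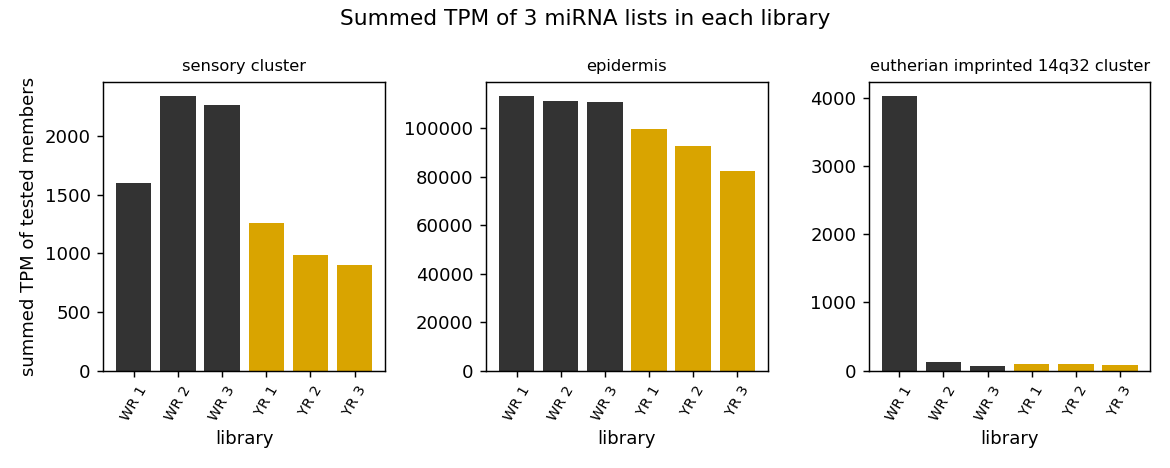
Summed TPM of the tested members of 3 lists in each library, bars from 0. The imprinted-cluster names reach 4033 TPM in WR replicate 1 and 67.7 to 121 TPM in the other libraries, while the sensory cluster lies between 1605 and 2348 TPM in WR and between 902 and 1256 TPM in YR.

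The ratio of x to y entries, read as 5p and 3p arms, passed the threshold for 2 of 112 pairs. Each entry sums a family number, so such a ratio cannot tell a change of arms from a change of family members. The 5p arm of miR-2184 gained on the 3p arm, the log2 ratio going from -0.29 ± 0.60 in WR to 1.99 ± 0.25 in YR (SD, n = 3 each; difference 2.28, SE 0.32; limma adjusted p = 0.0266), at levels of only 3.82 ± 1.0 and 7.30 ± 1.1 TPM for its 5p arm. The ratio of miR-15, a tumour-suppressing miRNA of mammals, went from 3.80 ± 0.01 to 4.60 ± 0.10 (difference 0.79, SE 0.14; limma adjusted p = 0.0447). Without single libraries the differences kept their sign, between 2.04 and 2.62 for miR-2184 and between 0.75 and 0.84 for miR-15. By limma 3 ratios passed without WR replicate 1, and 0 without any 1 of WR replicates 2 and 3 and YR replicates 1, 2 and 3, where 9 to 18 had an unadjusted p under 0.05.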

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

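Alternatives chosen after seeing the data were 1 entry per distinct sequence, without the imprinted-cluster names, library totals without TMM, GC offsets, and the 10 most abundant miRNAs of each library itself. The count of changed miRNAs, 44, was 16 with a mean of at least 10 TPM, 26 with quantile normalization, 76 with DESeq2, 21 with 1 entry per distinct sequence, and 0 among known miRNAs alone (edgeR; 52 at an unadjusted p under 0.05); these use fewer entries or another model, and the cause was not tested. In 11 other settings it lay between 30 and 50. Without single libraries it ran from 1 to 118. Same-numbered libraries of the groups had correlations of deviations of 0.26, -0.10 and 0.27, and not every library correlated best with its own number; with a replicate block 2 miRNAs, 1 arm ratio and 3 lists passed. The number of lists, 3, was 0 with an estimated correlation, 0 by fry (directional) and 7 by fry (mixed), and 2 to 4 without single libraries. The epidermis list, not past the threshold in the main result, passed in 12 of 26 alternatives, and the imprinted-cluster list missed it in 11 of 25. The variance options of limma do not enter camera. Limma on log2(TPM + 1), with its trend, without it and robust, thus gave the same list test, counted separately in these numbers. The imprinted-cluster list turned direction without WR replicate 1 (adjusted p = 0.424, from 5.26e-06 to 0.424 without single libraries). The number of arm ratios, 2, was 1 with a pseudocount of 0.1 TPM and 1 with both arms at 10 TPM or more, and ran from 0 to 3 without single libraries. The share of the 10 most abundant miRNAs kept its direction, between 2.98 and 5.14 percentage points higher in YR (4.17 in the main result; 3.06 with the 10 of each library itself, exact p = 0.2, where the groups overlap). Depth limits entries near 1 TPM, 7.88 to 9.94 reads per library.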

Other observations

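The tests on sequences read in a single group, on the imprinted-cluster names and on GC-dependent recovery were chosen after the result was seen; the trend of the predicted miRNAs with GC and the splits of miRNAs, lists and arm ratios were set before.

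In all, 17 distinct predicted sequences, TCTGGATCGATCTGTACGACA of the report among them, had at least 5 reads in every library of a group and at most 1 in every library of the other, 12 in WR and 5 in YR; 0 known names did. TTGCAGCTCTTACACTGTGGAC had 169, 162 and 144 reads in WR and 0 in YR, at least 169-fold higher in WR; CACTATGTAGGGAATAGGGCAC had 23, 17 and 30 against 0, at least 24.9-fold higher. In YR, ACGCAGCCGTAGACTACATATG had 25, 10 and 6 reads and GTCCCCTCACTCTGAAAGTGC 12, 12 and 11, both with 0 in WR. miR-8159-x (5.26 ± 1.43 TPM in WR, 0.280 ± 0.143 in YR) and miR-3074-x (4.68 ± 1.34 and 12.9 ± 1.57; SD, n = 3 each) also passed in the report's test and are named after their values were seen.

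Sequences read in a single group stand above counting error: 100 simulations with a shared mean gave at most 1 such sequence, against 17. For the 12 in WR, replicate 1 held 0.207 to 0.40 of the WR reads (median 0.341), against 0.952 for the imprinted-cluster names. The 5 with reads enough for a share above 0.8 lay between 0.323 and 0.37. These 12 were thus not read mainly in WR replicate 1. The shares cannot test reads of a mammal, because the selection asked for reads in every WR library and at most 1 in each YR library. The imprinted-cluster names, with 1068 and 608 counts in WR replicates 2 and 3 and 733 to 973 in the YR libraries, lack that spread. A sequence difference between the stocks stays open: 2 sequences had a listed partner with at most 2 mismatches, and 5.9% of the 17 had a partner read at least 10 times more in the other group. That pair is GCGACCCACCCATGATTTCAGT (25, 21 and 23 reads in WR, 0 in YR) and GCGACCCACTCATGATTTCAGA (0, 6 and 0 in WR, 166, 39 and 141 in YR), which differ by C10T and T22A, counted from 1 at the 5′ end of the first. A genotype difference in expression was not tested apart from this.

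Of the 40 imprinted-cluster entries with at least 20 reads, 40 were highest in WR replicate 1. RNA or reads of a mammal may be their source: of 34 mammalian entries outside the cluster, listed after the pattern was seen, 61.8% (95% exact interval 43.6 to 77.8) had that library over 3 times every other, such as miR-484-x with 1419 reads there and 55 to 194 elsewhere, against 10.1% of 425 remaining known names, not matched on GC. A difference between wild type and mutant is argued against as the source of this height, because WR replicates 2 and 3 lay on either side of YR. Summed over the tested entries they stood at 121 and 67.7 TPM, against 81.8 to 98.6 TPM in YR. The median log2 ratio of WR replicates 2 and 3 to YR was 0.026 over the 40 entries. Its 95% bootstrap interval, -0.20 to 0.12, covers the spread between entries, which are not independent, and not that between libraries. A small difference thus stays open. Which mammal cannot be told apart, since rodent names had 4502 reads there and 125 to 190 in each other library, but 0 entries bear the primate names that were to be compared. The choice between rodent and primate was set as undecided after this lack of entries was seen. In the authors' deposited table, 18 of the 96 miRNAs with an adjusted p under 0.05 have WR replicate 1 over 3 times every other library, among them miR-127-y (adjusted p = 0.0164 in that table); of all 85 such miRNAs with at least 10 reads tested here, edgeR called 0 (6 at an unadjusted p under 0.05), limma 0 and DESeq2 1.

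WR replicate 1 also had a trend with GC content of the sequence, Spearman rho 0.47 across 331 miRNAs of at least 10 TPM, against -0.32 to 0.05 in the other libraries; miRNAs are not independent replicates. Reads of a mammal are argued against as its whole cause, as 75 predicted trout miRNAs had rho 0.452 (95% bootstrap interval 0.26 to 0.62). GC-dependent recovery in that library stays open: rho was 0.503 in 247 known miRNAs outside the imprinted-cluster list, which belong to the trend itself and do not test it. With GC offsets 44 miRNAs passed, 31 of them among the 44 of the report. No biological explanation of this GC trend was tested.

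With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 44 miRNAs and the highest other 0, and 1 of the 10 splits gave as many. For arm ratios the values were 2 and 0, with 1 split as large, and for sequences read in a single group 17 and 1, with 1 split as large. For lists the real split put 3 past the threshold and the highest other 4, and 7 of the 10 splits gave at least 3. The 3 are the sensory cluster, neural and imprinted-cluster lists of the report. Their number thus does not set the real groups apart from other splits.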
